A study of Mus musculus with 73 samples.

How the data were processed

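Measured were RNA samples of 22 tissues of C57Bl6 mice, 10 to 12 weeks old, and of the mouse insulinoma line MIN6, each hybridized to 1 Affymetrix mouse array. The 73 arrays fell into 23 groups, with 3 arrays in 20 groups, 4 for muscle, 4 for bone marrow and 5 for pituitary gland. Per the series text, each tissue had at least 3 biological replicates, mainly from male mice, with female mice for placenta and ovary. Replicate numbers were taken to be separate samples, and no pairing between tissues was assumed.

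Per the labels' protocols, islet, pituitary gland and adrenal gland RNA was prepared with 1 microprep kit, MIN6 RNA with another kit, and all other RNA with Trizol followed by a column kit. Per the same protocols, RNA was reverse transcribed with an oligo-dT primer and transcribed in vitro to biotin-labelled cRNA. Per the submitters' processing notes, the images were processed in GCOS 1.4 with the MAS5 method. The deposited values were used as they were: signal intensities scaled by the authors, on a linear scale. Eye arrays differed in form, with decimals (medians of 55.7 to 57.3) and no zeros, while every other array held zeros. Whether the eye values were processed in another way was not tested. The mean signal after trimming 2% at each end was 149.1 to 149.6 on every array, which is the mark of the authors' scaling, and no further scaling was applied in the main results. Detection calls and raw image data were not used here. No 2 samples had identical values.

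Of 45037 probe sets in the table, 35877 were listed with a gene symbol, 34945 with 1 symbol and 932 with several, and 9160 had none. Of the probe sets with 1 symbol 34741 were matched by gene identifier, and no symbol changed. Probe sets with several symbols or none were left out of the gene tests and examined apart. The rest stood for 18193 genes. Probe sets above the median of the array on at least 3 arrays were kept, which left 17293 genes, and a gene was represented by its kept probe set with the highest mean log2 signal over all arrays. List genes without a probe set of their own were not analysed here. Cltrn is the current symbol of a list gene with an older name.

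Values were transformed to log2(signal + 16), so that log2 differences of genes with low signal are smaller than those of the signals themselves. One linear model per gene over all 23 groups was fitted with limma 3.58.1 in R 4.3.3, with an intensity trend in the variance. The model had 50 residual degrees of freedom and a prior of 11.8, and the median posterior SD was 0.32. For 1 tissue against every other, the largest of the 21 one-sided p values was taken, MIN6 was not among the comparators, and p values were adjusted over genes by the Benjamini-Hochberg method. A gene was called at an adjusted p below 0.05 and a gap of at least 1 log2 unit to the nearest tissue. Pairs of groups were tested in the same fit, 2-sided, with the same cutoffs. Sets of genes were tested with camera at its preset correlation of 0.01 and again with the correlation estimated from the data, adjusted over the 40 lists of a pair. A list call counted as kept only with both. Equality of all tissue means was tested with the F test of limma. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

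The 40 gene lists were fixed from general knowledge before the data were examined, but the list of islet-repressed genes comes from literature partly based on samples of this panel and is not independent of them. Also fixed by then were the comparisons, the cutoffs, the alternatives and the rule for naming genes. They cover markers of the tissues, other cell types, sex-linked genes, ribosomal protein genes, common reference genes, the cell cycle, energy metabolism and the secretory pathway. At the preset correlation camera called 8 lists for islets against acini, 12 for MIN6 against islets, 6 for heart against muscle and 3 for diaphragm against muscle. With the estimated correlation 6, 8, 2 and 0 of them were kept.

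Genes are named by rule. For islets against every other tissue these are the 15 called genes with the largest gap in each direction, and for each other tissue the gene with the largest gap in each direction. For each pair these are the 10 called genes with the largest difference in each direction. Genes picked by rank had to have all replicates on 1 side of all replicates of the group or groups compared. List members are given whether called or not. Counts under exchanged labels came from labels drawn anew over the tissue arrays, and from all possible splits for pairs. The tests of 1 tissue against every other had 100 draws, the real one included.

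The procedure was tried on simulated arrays drawn from the means and spread of the real genes, with differences of 1.5, 2 and 3 log2 units planted in 200 genes. For islets against every other tissue it recovered 92.5%, 98.5% and 100% of genes planted higher and all genes planted lower. Of the 17093 other genes it called 0, an outcome fixed beforehand because their islet mean was set to the average of the other tissues. That 0 therefore does not measure false calls. Genes planted lower had a signal well above background in every other tissue. Recovery of lower calls at low signal was not tried. For islets against acini all planted genes were recovered and 13 others were called. For MIN6 against islets 98.5% were recovered at the smallest difference and all at the larger ones, with 2 others called. For diaphragm and heart against muscle all were recovered, with 3 and 6 others called. In all pairs differences were planted only in genes whose mean log2 signal lay above the median gene of both groups. Recovery of genes with low signal was not tried for pairs. Sets were tried for diaphragm against muscle only: of 10 simulated sets of 20 moved genes 10 were called, and of 10 sets of unmoved genes 0 were called by camera. Genes of these sets also lay above the median gene. The simulated genes were drawn independently of each other, so false list calls under correlation between genes were not tried.

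Alternatives were a pseudocount of 1 and of 64, quantile normalization, no filter, a filter at the 75th percentile, the median over the probe sets of a gene, a minimum difference of 2 log2 units and of none, no intensity trend, replicate number as a block, a fit with only the 2 groups compared, other sets of comparator tissues, and each array left out in turn. Added after the data were seen were a run without 3 arrays that carried transcripts of another tissue and a run without acini among the tissues. Tissues were not measured in balance over RNA kits or array sets: 64 arrays also belonged to an earlier series, and the 9 arrays of islets, acini and MIN6 only to this one.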

Results

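The panel held 73 arrays from 22 mouse tissues and the mouse insulinoma line MIN6, with 3 arrays in 20 of the 23 groups, 4 for muscle, 4 for bone marrow and 5 for pituitary gland. Signals of 17293 genes entered the tests, each gene read on 1 probe set. A gene was called higher or lower in 1 tissue when it passed limma against each of the 21 other tissues with a gap of at least 1 log2 unit to the nearest of them, and in a pair when it passed limma between the 2 groups with a difference of at least 1 log2 unit. All log2 differences were taken on log2(signal + 16), a scale that shrinks differences at low signal. Where the lower group of a comparison is near background, the difference follows the signal of the probe set itself and the added 16, so that differences of separate genes do not rank them. With 3 to 5 arrays per group, the precision of every difference was limited by the number of arrays. Every array correlated with the others of its group at 0.894 or more, and the lowest values came from pancreatic acini. The 9 arrays of islets, acini and MIN6 belonged only to this series and the other 64 also to an earlier one, so the array set could not be separated from these groups. Islets, pituitary gland and adrenal gland shared 1 RNA kit, and MIN6 had a kit of its own.

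Pancreatic islets stood apart from 21 other tissues by genes of the beta cell, of the other endocrine cells and of hormone secretion. The beta-cell genes Ucn3, G6pc2 and Slc30a8, which encode a secreted peptide, a glucose-6-phosphatase and the zinc transporter of insulin granules, lay above every other tissue. The hormone genes Ppy, Pyy and Gcg and the transcription factor genes Nkx2-2 and Nkx6-1 followed. In the other direction, the lactate dehydrogenase gene Ldha and the monocarboxylate transporter gene Slc16a1, which carry pyruvate to lactate and lactate across the membrane in most cells, were lower in islets than in all 21 tissues. In total 106 genes were called higher and 22 lower in islets than in every other tissue by limma. These counts depended on the comparators and the settings. With MIN6 added as a comparator they were 21 and 2, and without brain, pituitary gland, adrenal gland and eye 287 genes were higher. By setting, a pseudocount of 1 gave 60 and 37, and 8 genes were lower with a pseudocount of 64 and also with the median over probe sets. Against adrenal and pituitary gland alone, the 2 tissues with the RNA kit of the islets, 803 genes were higher and 754 lower.

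Ucn3 averaged 4381 in islets and lay 7.43 log2 units above liver, the nearest tissue (adjusted p = 2.6e-36, limma). G6pc2 reached 11569 with a gap of 6.94 to acini. Slc30a8 reached 6357 with a gap of 6.88. Ppy averaged 15334 in islets, Pyy 8949 and Gcg 14299, with gaps of 6.16, 5.16 and 3.36. Gcg was nearest in acini, at 1425. Prss53 had a gap of 4.54, and Abcc8, which encodes the sulfonylurea receptor of the beta-cell potassium channel, had a gap of 4.07. Nkx2-2 averaged 1414 in islets and lay 3.83 above the next tissue. Nkx6-1 averaged 446 and lay 3.08 above. Kcnk16 and Trpm5, genes of a potassium channel and a cation channel, had gaps of 3.64 and 3.39. Sstr3 and Scn9a had gaps of 3.18 and 3.10, Sstr3 with brain as the nearest tissue. The nearest tissue of the 106 genes was acini for 25, pituitary gland for 24, brain for 10 and eye for 9.

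Of the fixed islet lists, transcription factors gave the largest share of genes higher in islets than in every other tissue. Counts were the same when p values were adjusted over the list alone. Of 12 transcription factor genes 9 were called by limma, among them Pdx1 (gap 2.89, nearest small intestine), Isl1 (2.49, eye), St18 (2.25) and Insm1 (1.92, pituitary gland). Neurod1, highest in eye, Pax6 and Hnf4a were not called. Of 9 hormone and prohormone-processing genes 4 were called: Gcg, Ppy, Sst (gap 3.04) and Iapp (gap 3.05). Ins2 was not called, because acini averaged 9347 against 5979 in islets and 3948 in MIN6. Pcsk1, Cpe, Scg5 and Pcsk1n were not called either. Of 11 glucose-sensing and channel genes 6 were called, with Glp1r at a gap of 1.88 and Gipr at 1.85 beside G6pc2, Abcc8, Trpm5 and Slc30a8. Slc2a2, the glucose transporter gene shared with liver, was 0.80 above liver and was not called. Kcnj11 was not called. Of 16 granule exocytosis genes 6 were called, among them Syt13 (gap 2.37) and Chga (nearest adrenal gland).

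Among genes lower in islets, Ldha averaged 86.7 against 764 in pituitary gland, the next lowest tissue, a gap of 2.91 log2 units (adjusted p = 4.4e-27, limma). Slc16a1 averaged 7.33 against 110 in acini, a gap of 2.47, on 1 of its 2 probe sets. Oat, the ornithine aminotransferase gene, averaged 129 against 673 in placenta, a gap of 2.25. Cxcl12 had a gap of 2.08 and 2 of its 3 probe sets carried the difference. Higd1a had a gap of 1.94 on 1 of 3 probe sets, and with the median over probe sets its gap turned to -0.72. C1qbp averaged 402 against 1175 in testis, and the acyl-CoA thioesterase gene Acot7 averaged 27 against 97.7 in salivary gland. The small ribosomal subunit gene Rps2 averaged 1560 in islets against 4218 in brain. Ogn, Pcolce and Pdgfra were called as well, Pcolce on 1 of its 2 probe sets. Nhp2 and Atad3a had gaps of 1.33 and 1.22. Mgst1 was called on 1 of its 2 probe sets, and its call was lost without brain array 3. The call of Igfbp4 was lost without islet array 2, and that of Cp without islet array 1 or testis array 1. The number of genes called lower ranged from 18, without islet array 2, to 23 when 1 array was left out.

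A literature list of 27 genes repressed in islets was partly chosen on samples of this panel, and its counts are therefore not independent evidence. Of these genes 10 were called lower in islets than in every other tissue by limma, and the same 10 when adjusted over the list alone: Ldha, Slc16a1, Acot7, Pdgfra, Igfbp4, Oat, Cxcl12, Mgst1, Cd302 and Tgm2. Islets had the lowest mean of the 22 tissues for 23 of the 27. In MIN6, Ldha was at 704, Oat at 201, Cxcl12 at 80 and Acot7 at 14.7. Of the 22 genes low in islets, 2 were higher in MIN6 than in islets and 5 were lower. Of the 106 genes high in islets, 4 were higher in MIN6 and 28 lower, with a median difference of -0.46 log2 units. Pyy averaged 29.7 in MIN6 and Gcg 228. Nkx6-1 averaged 1603 and Nkx2-2 averaged 2590, above the islet means.

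**Figure D1:**
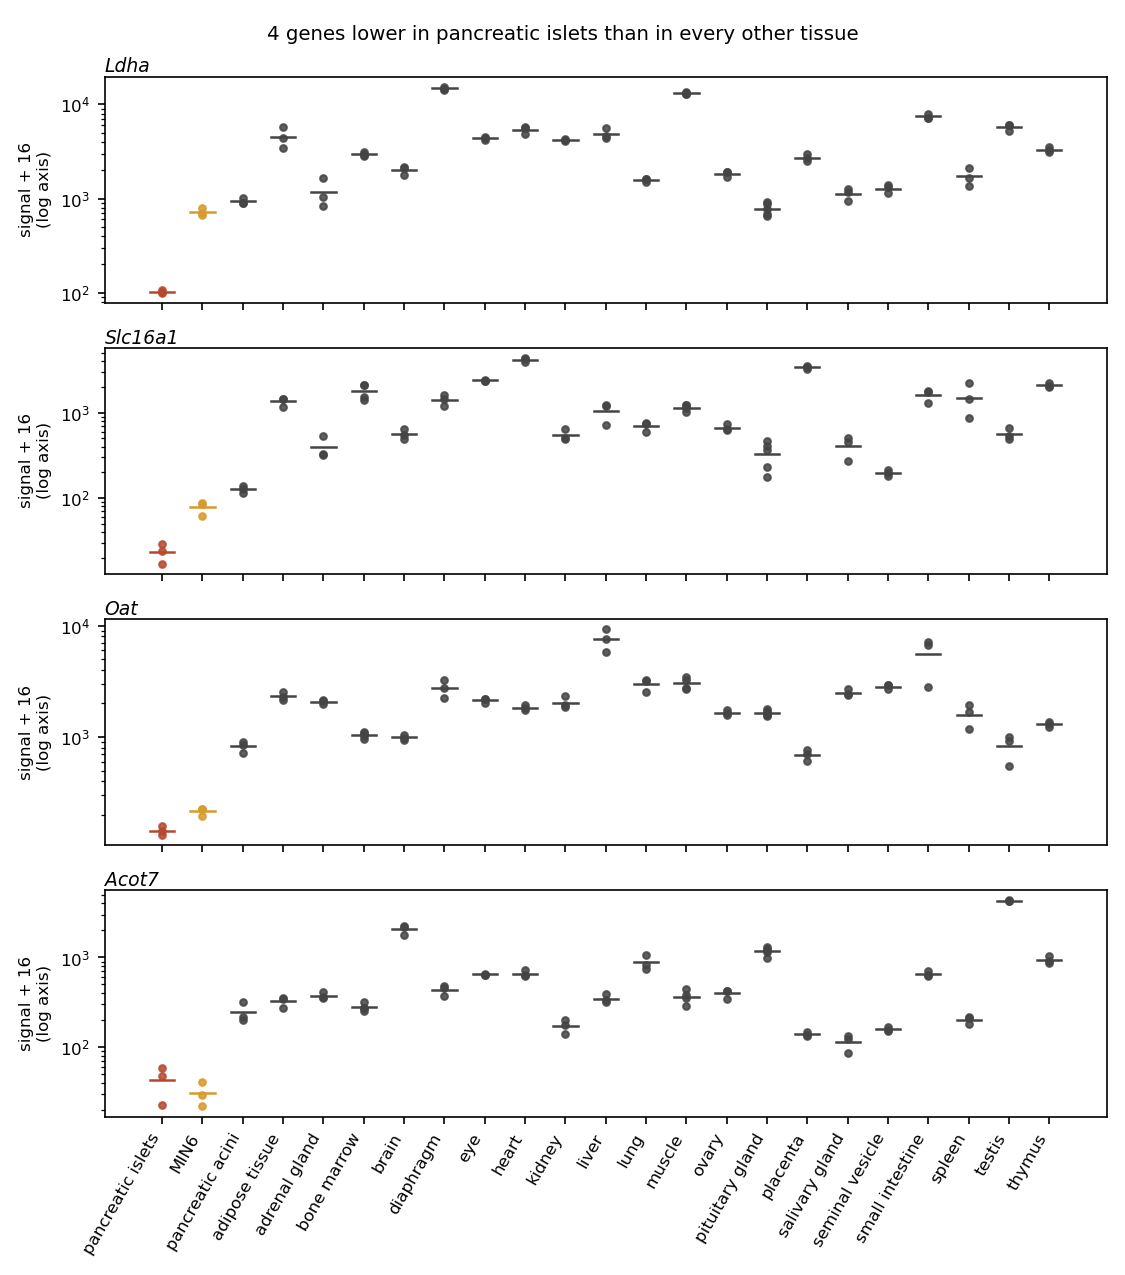
Signal plus 16 of Ldha, Slc16a1, Oat and Acot7 on each array, log axis. Bars are group means, with islets in red, MIN6 in orange and the 21 other tissues in grey.

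Every tissue had genes that lay above all others, and the leading gene was in most cases a known product of that tissue. Testis had the most such genes, and diaphragm and muscle, both made of skeletal muscle fibres, the fewest. Summed over the 22 tissues, 4441 calls of a gene higher in 1 tissue than in every other were made by limma, of which testis gave 1515 (34.1%). Brain had 451, liver 303, acini 248, placenta 243 and small intestine 229. Eye had 208, kidney 172, bone marrow 170, lung 105, spleen 104 and thymus 95. Seminal vesicle had 86, adipose tissue 81, salivary gland 78, heart 71, ovary 67, adrenal gland 52 and pituitary gland 51. Muscle had 4 and diaphragm 2. Lower calls numbered 835, and testis gave 597 of them (71.5%). The total of lower calls was 1347 with a pseudocount of 1, 329 with a pseudocount of 64 and 535 with the median over probe sets. Acini followed with 70, liver with 52, brain with 25 and bone marrow with 19. In 7 tissues no gene was called lower by limma.

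**Figure D2:**
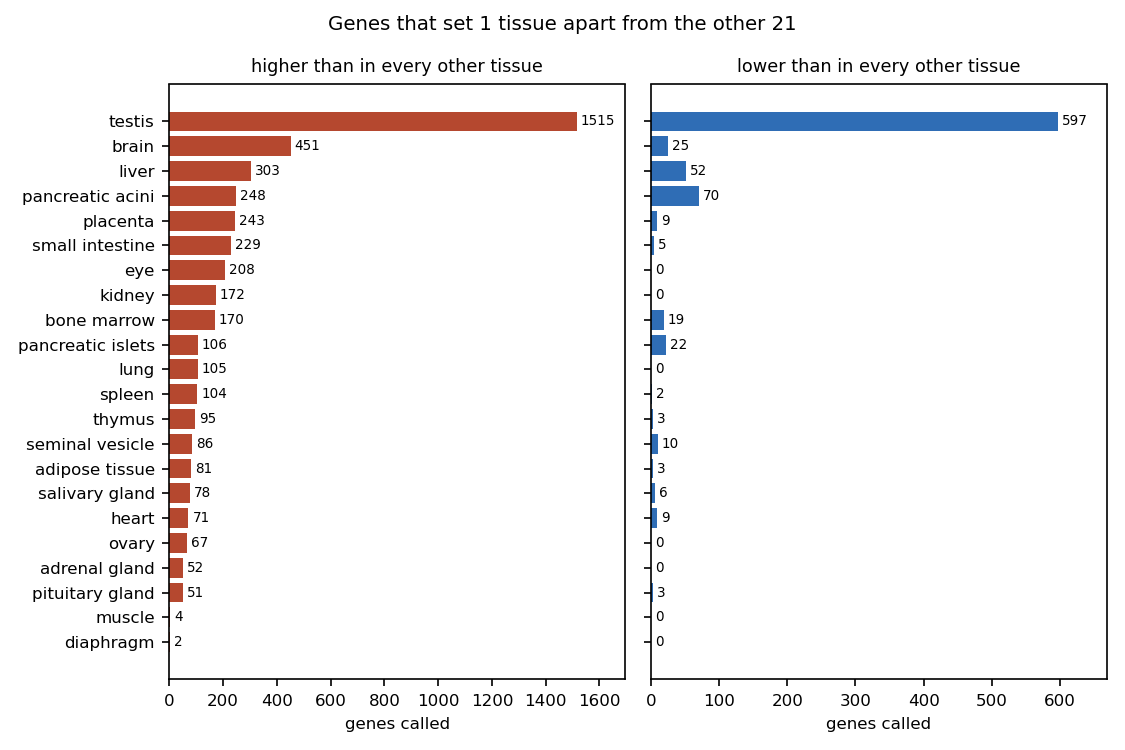
Genes called higher (red) or lower (blue) in 1 tissue than in every other of the 22 tissues.

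Smr3a, a salivary peptide gene, averaged 27683 in salivary gland with a gap of 10.16 log2 units. Pate4 averaged 29553 in seminal vesicle with a gap of 9.94. Cga, the shared subunit gene of pituitary glycoprotein hormones, averaged 14294 in pituitary gland with a gap of 8.88. Cyp11b1, the steroid 11-beta-hydroxylase gene, averaged 9789 in adrenal gland with a gap of 6.57. Ptf1a, the acinar transcription factor gene, averaged 6588 in acini against 133 in islets. Leading genes elsewhere were Crygd in eye (gap 8.95), Akr1c6 in liver (8.95), Prl7a2 in placenta (8.75), Hspb9 in testis (8.14) and 2010106E10Rik in small intestine (7.11). Umod led in kidney (gap 7.08), Sftpa1 in lung (6.96), Pln in heart (6.76) and Prg2 in bone marrow (6.65). Ovgp1 led in ovary (6.03), Lep in adipose tissue (5.90), Ddn in brain (5.34), Tbata in thymus (5.32) and Cr2 in spleen (4.23). Ucp3 averaged 1254 in diaphragm against 516 in muscle, a gap of 1.26 (adjusted p = 0.0046, limma). Mustn1 averaged 1695 in muscle against 416 in diaphragm, a gap of 1.74 (adjusted p = 0.0042, limma). The Ucp3 call was lost without diaphragm array 1 or muscle array 1, and the Mustn1 call without diaphragm array 1, muscle array 1 or muscle array 4.

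Genes lowest in 1 tissue were led by 2 abundant transcripts. Malat1, a nuclear noncoding transcript, averaged 33.3 in testis against 649 in acini, the next lowest tissue, a gap of 3.74 log2 units. Pkm, the pyruvate kinase gene of most tissues outside liver, averaged 22.7 in liver against 375 in acini, a gap of 3.43. Nxf1 averaged 10 in acini against 113 in heart. Rps27l averaged 345 in brain against 1162 in eye. Slc38a10 in seminal vesicle (gap 1.84, 3 of 7 probe sets), Neo1 in bone marrow (1.74, 3 of 5 probe sets), Gstt1 in placenta (1.54), Surf6 in heart (1 of 2 probe sets), Tbcel in salivary gland (1.43) and Gstm5 in thymus (1.37) were also called. The Surf6 call was lost without small intestine array 1. Hook1 in adipose tissue (1.34), Ttc7b in small intestine (1.29) and Ctf1 in spleen (1.22) had the smallest gaps. Sf1 was lower in pituitary gland by a gap of 1.45 on 1 of 5 probe sets, and its gap turned to -0.69 with the median over probe sets.

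Fixed lists of known marker genes were high in their own tissue for most glands and organs. Counts give genes called higher than every other tissue by limma, of those measured, and were the same adjusted over the list alone except where stated. All 11 pituitary genes, all 14 testis genes, all 8 seminal vesicle genes and all 6 placenta genes were called. Acinar enzymes had 18 of 21, bone marrow 11 of 12, eye 12 of 13, lung 8 of 9, spleen 7 of 8, kidney 9 of 11, thymus 10 of 12 and liver 13 of 16. Cardiac muscle had 11 of 16, salivary gland 6 of 9, adrenal gland 7 of 11 and brain 5 of 10. Small intestine had 9 of 13 (10 adjusted over the list alone), adipocytes 5 of 8 (6 adjusted over the list alone) and ovary 4 of 12 (6 adjusted over the list alone). The skeletal muscle list had 0 of 12 called in muscle by limma, and the slow fibre list 0 of 11 in diaphragm. Diaphragm and muscle were comparators of each other, so a gene of similar level in both could not be called in either. These 2 counts therefore do not measure how well the lists mark muscle.

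Between islets and acini, the endocrine and the exocrine parts of the pancreas, genes of hormone secretion were higher in islets. Acinar enzyme genes were higher in acini, but their list call was lost with an estimated correlation, and after quantile normalization 7 of 21 stayed lower in islets by limma. Scg3 and Scg5, which encode granule proteins of endocrine cells, and the transcription factor gene Isl1 were higher in islets. Ptf1a, the cholecystokinin receptor gene Cckar and the chymotrypsin gene Ctrc were on the acinar side. Acinar enzyme transcripts were also high in the islet arrays: Ctrb1 averaged 12414 in islets, Cela2a 13591 and Cpa1 11136. By limma 2780 genes were higher and 4254 lower in islets than in acini, so that 39.5% of the called genes were higher. The median gene differed by -0.25 log2 units, and relative to it 3593 genes were higher and 3137 lower. After quantile normalization the counts were 3299 and 3211, or 50.7% higher, and with a pseudocount of 64 they were 1892 and 1964, or 49.1% higher.

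**Figure D3:**
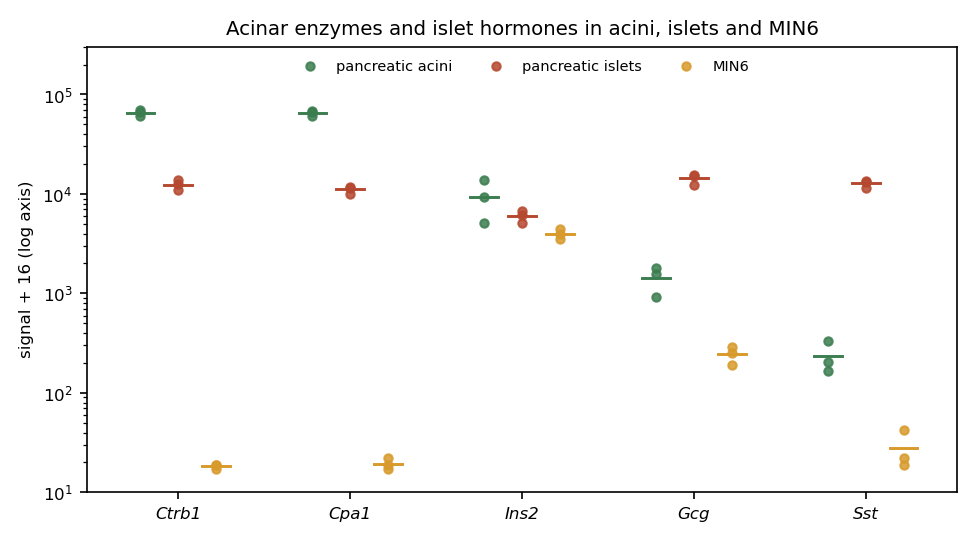
Signal plus 16 of Ctrb1, Cpa1, Ins2, Gcg and Sst in acini (green), islets (red) and MIN6 (orange), log axis. Points are arrays and lines are group means.

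On the islet side, Resp18 was higher by 7.93 log2 units (9438 against 32), Scg3 by 7.79, Ucn3 by 7.71 and Scg5 by 7.48. Isl1 averaged 3132 in islets and 5.33 in acini. Slc2a2 averaged 6901 in islets and 49.3 in acini. Papss2, Emb, G6pc2 and Slc30a8 were higher in islets as well. In the hormone list 8 of 9 genes were higher in islets, with a median of 4.31 (camera adjusted p = 0.00032 with an estimated correlation). Ins2, the remaining gene, was not called (adjusted p = 0.13, limma). Of 12 transcription factor genes 11 were higher, with Isl1, Pdx1 and Nkx6-1 among them, and Hnf4a was lower. Glucose-sensing and channel genes were higher for 10 of 11, with a median of 4.04, and Kcnj11 was not called. Granule exocytosis genes were higher for 14 of 16, with a median of 3.57 (camera adjusted p = 2.4e-05 with an estimated correlation). Stx1a was lower, a call lost without acini array 1 or 3 or islet array 1 or 3. These lists kept their calls with an estimated correlation.

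On the acinar side, the hepcidin gene Hamp2 averaged 7451 in acini and 71 in islets, and Cckar averaged 11180 and 198. Vtn averaged 4311 in acini and 88 in islets. Ctrc averaged 21124 in acini and 502 in islets. Tmed11, Slc39a5, Aldh1a7, Klk1b5 and 1810007D17Rik were also higher in acini. All 21 acinar enzyme genes were lower in islets, with a median of -2.96, and the list call was lost with an estimated correlation (camera adjusted p = 0.25). After quantile normalization 7 of the 21 were lower, and the differences of Ctrb1, Cela2a and Cela1 turned to 0.04, 0.06 and 0.04. Their acinar signals lay above the highest signal of any array outside acini: Ctrb1 averaged 65738, Cela2a 74440 and Cpa1 65485. The acini arrays reached 86914 to 100155, and the top signal of every other array was at most 42547. The islet arrays reached 18420 to 19331. Ctrb1 and Cela2a were thus among the strongest signals in both groups, where quantile normalization, which matches arrays by rank, removes a difference. It therefore cannot decide whether these enzymes differed. Of the 27 literature genes repressed in islets 21 were lower in islets than in acini, and because the list was partly chosen on samples of this panel its camera p value is not a test of that pattern.

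Genes of protein synthesis differed in the same direction as the enzymes. Of 25 ribosomal protein genes 21 were lower in islets, with a median of -1.52 (camera adjusted p = 0.048 with an estimated correlation). After quantile normalization the list call was lost (camera adjusted p = 0.35 with an estimated correlation), 4 of the 25 were lower with a median of -0.31, and Rplp0, Rpl13a, Rpl41, Rps14 and Rps29 turned to 0.07, 0.22, 0.05, 0.07 and 0.31. Eef1a1 was lower in islets by -1.92 and turned to 0.15. Rps29, Rpl41 and Eef1a1 averaged 44650, 37551 and 45025 in acini, above the top islet signal of 19331. Quantile normalization, which gives all arrays 1 distribution, was bound to shrink such differences. In the list of the unfolded protein response and secretory pathway 9 of 20 genes were lower in islets, led by Edem1 (-2.97) and Creld2 (-2.53), and Dnajb9 (1.55) was higher. Trib3 was also higher, a call lost without acini array 1. The list call was lost with an estimated correlation (camera adjusted p = 0.42). Hspa5 fell by 1.77 and Xbp1 was lower, and both turned after quantile normalization, to 0.0114 and 0.00753.

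Lists of energy metabolism and of other cell types were not called between islets and acini by camera. Of 18 glycolysis genes 5 were higher in islets, among them Pkm (2.24), Eno2 and Pfkp, and 5 lower, among them Ldha (-3.20), Slc16a1 (-2.47) and Slc16a3 (-2.29). Of 22 genes of the TCA cycle and oxidative phosphorylation 3 were higher, led by Cox6a2 (2.97), and 4 lower, led by Cox5a (-1.77). Fatty acid oxidation had 1 higher and 2 lower of 12. Of 11 endothelial genes 4 were higher in islets, with Plvap at 2.53 and Emcn at 2.20. Fibroblast and matrix genes were lower for 7 of 10, with Dcn at -3.24, and 2 were higher. Of 7 duct genes 5 were lower, with Muc1 at -4.76 and Krt19 at -3.09, and Krt7 was higher at 3.89. Smooth muscle had 3 lower of 6, leukocytes 2 higher and 1 lower of 12, erythroid genes 1 lower of 3 (Slc4a1) and sex-linked genes 1 higher of 4. Cell cycle genes had 2 higher and 5 lower of 23.

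MIN6 differed from islets in the fixed lists of the cell cycle, of glycolysis and of several other cell types of the pancreas. MIN6 is a tumour line of dividing cells, and the proliferation genes Mki67, Top2a and Mcm3 were higher in it. Ldha, Slc16a1 and Slc16a3, members of the glycolysis list for lactate production and transport, were also higher. The hormone genes Sst, Gcg and Ppy of the other islet cells were lower, as were the acinar enzyme genes. By limma 1160 genes were higher and 1431 lower in MIN6 than in islets, so that 44.8% of the called genes were higher. The median gene differed by -0.08, and relative to it 1345 genes were higher and 1246 lower. After quantile normalization the counts were 1240 and 1195, or 50.9% higher, and with a pseudocount of 64 they were 695 and 685, or 50.4% higher. MIN6 and islets correlated at 0.901 over gene means, and each was the other's nearest group.

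Cck averaged 4226 in MIN6 and 15.3, near background, in islets, and Igf2 averaged 5996 and 81. Dlk1, Blnk, Prmt8, Meox2, Hpca, Gm13889, Mcm3 and B3gat1 were also higher in MIN6. Of 23 cell cycle genes 22 were higher in MIN6, with a median of 3.16 (camera adjusted p = 0.0019 with an estimated correlation). Mki67 averaged 981 in MIN6 and 83.7 in islets, and Top2a was higher by 3.87. Of 18 glycolysis genes 10 were higher, with a median of 1.46 (camera adjusted p = 0.0047 with an estimated correlation). Slc16a3 averaged 321 in MIN6 and 9.67 in islets, Ldha was higher by 2.81 and Slc16a1 by 1.77. Hk1 was lower by -1.76.

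The enzyme genes Ctrb1, Cela2a and Cpa1 were near background in MIN6, and of 21 acinar enzyme genes 20 were lower than in islets (median -8.43; camera adjusted p = 0.00054 with an estimated correlation). Cpb1, Reg1, Rnase1, Ctrl, Cela1 and Prss2 were lower too. Ctrb1 averaged 2.33 in MIN6. Of 9 hormone genes 4 were lower, Sst by -8.94 (11.7 against 12738), Gcg by -5.89, Ppy by -2.80 and Pcsk1, the last a call lost without islet array 2 or MIN6 array 3. Ins2 and Iapp were not called. Endothelial genes were lower for 10 of 11, with Emcn at -5.16 and Plvap at -4.52. Leukocyte genes were lower for 10 of 12, with H2-Aa at -5.52, and fibroblast genes for 8 of 10, with Sparc at -4.43. The Y-linked genes Eif2s3y, Uty and Kdm5d were lower, and these 3 made up the called genes of the 4 measured in the sex-linked list. Each of these 5 lists kept its call with an estimated correlation, the hormone list at an adjusted p of 0.033 by camera.

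Genes of beta-cell identity went both ways between MIN6 and islets. Of 12 transcription factor genes 4 were higher in MIN6, Nkx6-1 by 1.81, Pdx1 by 1.25, Neurod1 by 1.06 and Insm1, the last a call lost without MIN6 array 2. Of 11 glucose-sensing and channel genes 2 were lower, Slc2a2 by -2.13 (1564 against 6901) and Gipr by -1.44. Of 16 granule exocytosis genes only Syt7 was called, higher in MIN6. Literature-repressed genes were higher in MIN6 for 4 of 27 (Ldha, Slc16a1, Parp3 and Zyx) and lower for 10. None of these 4 lists was called by camera. Lists called only with the preset correlation were the secretory pathway (8 of 20 lower, Sdf2l1 by -2.60; camera adjusted p = 0.064 with an estimated correlation), the TCA cycle (3 higher and 1 lower of 22), the common reference genes (4 higher and 1 lower of 12) and the salivary list (3 lower of 9, Egf by -3.01 and Amy1 by -2.79). With an estimated correlation the adjusted p was 0.64 for the TCA cycle, 0.051 for reference genes and 0.051 for the salivary list by camera. Ribosomal protein genes had 0 of 25 called by limma.

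Heart and muscle, 2 striated muscles with separate sets of contractile genes, differed in the fixed lists of cardiac and of skeletal muscle genes. Myh6, Tnni3 and Tnnt2, the myosin and troponin genes of the heart, were higher in heart. Tnnt3, Actn3 and Myh4, genes of fast skeletal fibres, were higher in muscle. The natriuretic peptide genes Nppa and Nppb were on the heart side. By limma 2633 genes were higher and 1089 lower in heart than in muscle, so that 70.7% of the called genes were higher. The median gene differed by 0.28 log2 units, and relative to it 1369 genes were higher and 1746 lower. After quantile normalization the counts were 1526 and 1393, or 52.3% higher, and with a pseudocount of 64 they were 885 and 746, or 54.3% higher.

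All 16 cardiac genes were higher in heart, with a median of 5.82 (camera adjusted p = 5e-11 with an estimated correlation). Myh6 averaged 21040 in heart and 15.3 in muscle, and Pln averaged 16791 and 73. Tnni3 was higher by 8.88, Tnnt2 by 7.98, Nppb by 7.97, Nppa by 7.75, Ryr2 by 7.58, Mybpc3 by 7.16 and Fhl2 by 7.05. Ptgds was higher by 6.72. Skeletal muscle genes were lower in heart for 11 of 12, with a median of -8.27 (camera adjusted p = 1.2e-05 with an estimated correlation), and Ckm was not called. Tnnt3 averaged 14.3 in heart and 22293 in muscle, and Actn3 (-9.41), Myh4 (-9.18), Tnnc2 (-8.82), Myh1 (-8.79), Ryr1 (-8.60), Neb (-8.48), Mylpf and Pvalb (-8.24) were lower as well. Slow fibre genes went both ways, with Casq2 (3.96), Atp2a2 (2.55), Myl2 (2.08), Tnnc1 and Myl3 higher in heart and Tnni1 (-5.57), Tnnt1 (-3.54) and Myh7 (-1.48) lower. Myh2, which the fixed list also holds although it encodes a fast myosin of oxidative fibres, was lower by -8.88.

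Fuel genes were split between heart and muscle. Of 18 glycolysis genes 6 were higher in heart, among them Hk1 (2.85), Pfkl (2.54), Pfkp (2.50), Ldhb (2.27) and Slc16a1 (1.87). Lower in heart were 7, among them Slc16a3 (-4.41), Pkm (-1.57), Pfkm (-1.31) and Ldha (-1.28), and the list was not called by camera. Fatty acid oxidation genes were higher in heart for 5 of 12, with Hadha at 1.51 and Decr1 at 1.43, and Ucp3 was lower by -1.29. Of 22 genes of the TCA cycle and oxidative phosphorylation 3 were higher, Ppargc1a by 1.53, Cox6a1 by 1.36 and Cox7a1 by 1.10. Leukocyte genes were higher in heart for 8 of 12. Ovary genes were higher for 7 of 12, with Fshr at 1.92. Signals of that list were low, with log2 medians of 6.33 in heart and 5.10 in muscle. The median of all genes was 6.78 in heart and 6.35 in muscle. The calls of the last 4 lists were lost with an estimated correlation (camera adjusted p = 0.31, 0.74, 0.78 and 0.26).

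Diaphragm and muscle were the closest pair of tissues by correlation and by genes called, and no gene of the skeletal muscle or slow fibre lists was called between them by limma. Their gene means correlated at 0.985, and 151 genes were called between them against 2882 between islets and pituitary gland, the pair with the next fewest genes called. The nuclear receptor gene Nr4a3 and the genes Pdia4 and Sdf2l1, whose proteins act in the endoplasmic reticulum, were higher in diaphragm, Pdia4 on 1 of its 2 probe sets. The stretch-responsive gene Ankrd1, the matrix gene Lum and Mustn1 were higher in muscle. By limma 83 genes were higher and 68 lower in diaphragm, or 55.0% higher, and after quantile normalization 67 and 128, or 34.4% higher. The counts moved with several settings, to 164 and 192 with a pseudocount of 1, 15 and 13 with a pseudocount of 64, and 47 and 37 with only these 2 groups in the fit. Without diaphragm array 2 they were 126 and 119.

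Nr4a3 averaged 697 in diaphragm and 71.5 in muscle, a difference of 2.70 log2 units, with an SD of 589 in diaphragm. Of its 3 probe sets 2 went in this direction. Tmem87a differed by 2.66, and its call was lost without diaphragm array 2. Pdia4 averaged 133 in diaphragm and 26.8 in muscle. Sdc4 averaged 349 and 112. Rrp9 (1.95), Sco2 (1.63) and Sdf2l1 (1.49) were higher as well, with Ptprcap and H2-Oa. Ankrd1 averaged 122 in diaphragm and 610 in muscle, and Lum 329 and 1043. Dusp10 was lower by -1.61. Wfdc17, 2410006H16Rik and Eda2r were also lower in diaphragm. The call of Dnajc22 was lost without each of 6 of the 7 arrays in turn, and Prss2, Ccl8 and Tmem232 also lost theirs without 1 array. Skeletal muscle genes had 0 of 12 called by limma, and slow fibre genes 0 of 11. Myh7, the slow myosin gene, averaged 1997 in diaphragm and 2812 in muscle and was not called. Of 12 fatty acid oxidation genes Ucp3 was called. Smooth muscle genes (0 of 6 called, median 0.62), leukocyte genes (0 of 12 called, median -0.25) and the secretory pathway (2 of 20 called) were called as lists by camera, and each call was lost with an estimated correlation (adjusted p = 0.91, 0.98 and 0.98).

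Genes often used as references ranged from the actin gene Actb, among the most even of all genes, to the histocompatibility light chain gene B2m, and the median range of these genes was close to that of all genes. Over the 22 tissue means the 12 common reference genes had a median range of 3.22 log2 units, the 25 ribosomal protein genes 2.48, and all 17293 genes 3.30. Among the 4324 genes with the highest signal the median range was 3.03. The combined median range of reference and ribosomal protein genes was 2.57, and 1.97 after quantile normalization. The F test of limma over the tissues did not set these genes apart, as 17271 of all genes passed it. Some ribosomal probe sets lay near background, such as that of Rps16 with tissue means of 0.667 to 39.4, and their ranges do not measure the transcript. The most even reference gene was Actb, with a 2.17-fold range on signal + 16 (14547 in acini, 6704 in kidney). Polr2a had a range of 3.28-fold, Eef2 5.16, Sdha 6.01, Hprt 7.65, Ywhaz 8.39, Eef1a1 10.3 and Tbp 11.7. B2m ranged 32.9-fold, from 945 in testis to 30905 in seminal vesicle. Pgk1 ranged 26.5-fold, from 352 in testis to 9722 in muscle. Tfrc ranged 23.8-fold and Gusb 19.7-fold. Among ribosomal protein genes Rps4x ranged 32.7-fold (800 in testis, 26406 in acini), Rpl41 15.8-fold and Rps2 10.9-fold, and Rps14 3.30-fold. The most even of all genes, chosen after the values were seen, were Safb (1.63-fold), Rbm6 (1.78-fold) and Prpf6 (1.81-fold).

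**Figure D4:**
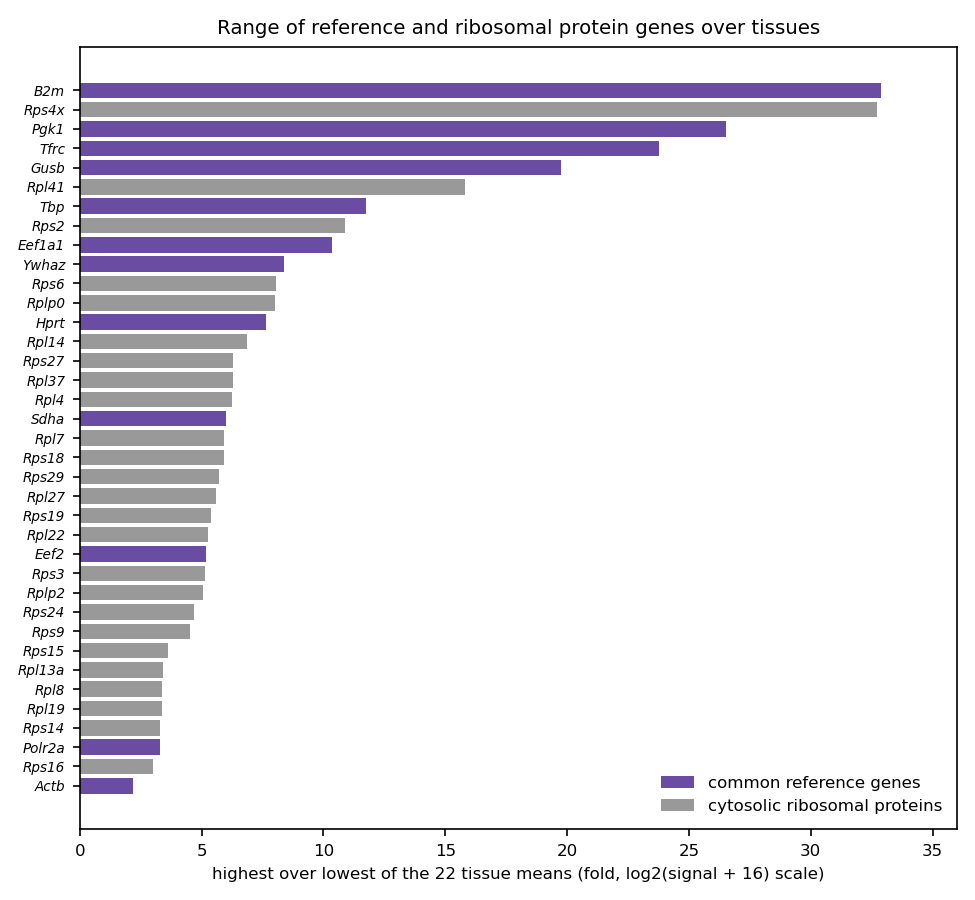
Fold between the highest and the lowest of 22 tissue means, on signal plus 16, for 12 common reference genes (purple) and 25 ribosomal protein genes (grey).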

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

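The splits with exchanged labels and the search for values standing apart within a group were planned; the tests on transcripts of other tissues, on exchanged labels of arrays, on RNA kit and array set, on other cell types and on the signal ceiling were chosen after the results had been seen.

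In the splits, the real grouping gave the largest count each time. For islets 106 genes were called higher and 22 lower by limma, and no other draw of labels gave any, so that only the real one of 100 draws reached its count in either direction (1 of 100 for higher and 1 of 100 for lower). Over all tissues the real 4441 higher calls compared with 286 at most (1 of 100) and the real 835 lower calls with 0 (1 of 100). These draws mixed different tissues within each group, which widened the spread within groups and brought the group means together. Few calls were thus bound to result, and the draws do not measure calls arising by chance from the spread of replicates. Between heart and muscle 3722 genes were called and at most 2464 in another split (1 of 35), and between diaphragm and muscle 151 and at most 57 (1 of 35). Every other split put arrays of both tissues into the same group, which brought the group means together. The real split was thus favoured beforehand, and these splits do not measure calls arising by chance either. The same holds between islets and acini (1 of 10 splits) and between MIN6 and islets (1 of 10 splits), where the splits were also too few.

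Values standing apart were searched for among named genes, and only in muscle, bone marrow and pituitary gland, the groups with more than 3 arrays. Groups of 3 arrays, among them islets, acini, MIN6, heart and diaphragm, were not searched. Of 44 values tested for standing apart within their group 6 did, and 2.2 were expected at 1 in 20. Most of the 44 were muscle values, so the number found in muscle does not set that tissue apart. Sf1 was 1069 on pituitary array 4 against 619 to 720 on the others (gap over range 0.724). Nr4a3 was 37 on muscle array 3 against 78 to 86 (0.875). Tmem87a was 23 on muscle array 2 against 2 to 3 (0.930). Myh6 was 23 on muscle array 1 against 12 to 13 (0.894). Pln was 68 on muscle array 2 against 74 to 75 (0.862). Mybpc3 was 8 on muscle array 3 against 40 to 43 (0.942). Among 7101 probe sets with no gene or several genes, 25 were higher and 4 lower in islets than in every other tissue by limma.

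Transcripts of another tissue stood out on 3 arrays: Ctrb1 was 1602 on spleen array 2 against 6 and 29 on the others, Prm1 was 1271 on adrenal array 1 against 21 and 4, and Adipoq was 4216 on adrenal array 3 against 436 and 760. Among genes of the source tissue outside the fixed lists, the share raised by at least 1 log2 unit over both other replicates was 25% for acini on spleen array 2 (8 of 32 genes), 38.0% for testis on adrenal array 1 (104 of 274) and 36.4% for adipose tissue on adrenal array 3 (4 of 11). On adrenal array 3 bone marrow genes were raised too (40%, 8 of 20). Over the other combinations of array and source tissue the highest share was 18.8%, for seminal vesicle genes on acini array 1 (3 of 16). The margin of spleen array 2 over it rested on few genes. These shares are consistent with carry-over of tissue or RNA, and exchanged whole arrays are argued against, because each of the 3 correlated better with its own group than with any other array, by 0.0679 at least. At which step the transcripts entered stays open. The search compared each array with the other replicates of its group, so transcripts of another tissue shared by all replicates could not be found. Muscle and diaphragm, with 4 and 2 called genes, fell short of the 10 genes needed for a source tissue. The other arrays are therefore not shown to be free of such transcripts.

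The 22 genes low in islets could come from the RNA kit, the array set or a lack of surrounding cells. The RNA kit is argued against: over 25 genes picked without adrenal and pituitary gland, these 2 tissues with the same kit were shifted by -0.21 from the Trizol tissues of the earlier series and islets by -3.30. Over 28 genes picked without acini, acini, from the same array set, were shifted by -1.89 and islets by -3.42, so a part played by the array set stays open. A lack of all other cell types is argued against by the endothelial genes alone, for which islets had rank 13 from the lowest of 22 tissues. Fibroblast genes had rank 1, smooth muscle genes rank 2 and leukocyte genes rank 4, so a lack of these cells could lie behind genes such as Pdgfra, Ogn and Pcolce and stays open.

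Acinar enzyme transcripts in the islet arrays fit acinar cells left in the preparation: of 21 acinar genes outside the enzyme list 18 (85.7%) were at least 1 log2 unit higher in islets than in MIN6. The median share of the acinar signal found in islets was 15.8% for 16 genes above 60000 in acini and 2.84% for 14 genes of 5000 to 25000, that is 5.56 times as high. A ceiling on the strongest signals could produce this, and it would make the fall of Ctrb1 and Cela2a in islets too small. The amount of acinar tissue in the islets therefore stays open.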

How the results depend on the processing

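Most counts depended on the minimum difference and on the pseudocount, and the directions of named genes much less. Of 65 gene results for 1 tissue against every other, 31 kept their call in every alternative run for them, and of 641 in pairs 357. Changes of the minimum difference were run for counts only and not for these gene results. Changes of the comparator tissues were run for only a part of the 65. No filter, a filter at the 75th percentile and limma without an intensity trend moved no count by a factor of 1.5 or more. Where a count moved, the cause was not tested unless stated.

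With a pseudocount of 1, islets had 60 genes higher and 37 lower than every other tissue, all tissues together 1347 lower, and diaphragm against muscle 164 and 192. With a pseudocount of 64, islets had 8 lower, all tissues 329 lower, islets 1964 lower than acini, MIN6 695 and 685, diaphragm 15 and 13, and heart 885 higher. With a minimum difference of 2 log2 units, islets had 42 and 4, all tissues 2229 and 75, islets against acini 929 and 998, MIN6 321 and 401, diaphragm 2 and 0, and heart 272 and 273 by limma. With no minimum difference, islets had 41 lower, all tissues 1923 lower, islets against acini 4744 and 6670, MIN6 2906 and 3092, diaphragm 495 and 535, and heart 5995 and 2826.

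Quantile normalization gave 128 genes lower in diaphragm, 1526 higher in heart, and a median range of reference and ribosomal protein genes of 1.97 log2 units instead of 2.57. It turned the sign, islets minus acini, of Cela1 (0.0420), Cela2a (0.0590), Ctrb1 (0.0355), Rplp0 (0.0673), Rpl13a (0.222), Rpl41 (0.0513), Rps14 (0.0734), Rps29 (0.315), Eef1a1 (0.149), Hspa5 (0.0114) and Xbp1 (0.00753). The median over probe sets gave 8 genes lower in islets and 535 lower over all tissues. It turned the gap of Higd1a in islets to -0.72 and of Sf1 in pituitary gland to -0.69, and the islet minus acini difference of Pdgfrb to -0.30, of Dntt to 0.22 and of Ogdh to -0.81.

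A fit with only the 2 groups compared gave 47 and 37 genes for diaphragm against muscle. Without brain, pituitary gland, adrenal gland and eye as comparators, islets had 287 genes higher. With only adrenal and pituitary gland they had 803 higher and 754 lower. With MIN6 added as a comparator they had 21 and 2, and the gap turned for Nkx2-2 (-0.87), B830017H08Rik (-0.41), Trpm5 (-0.0107), Nkx6-1 (-1.811), Higd1a (-2.78), Acot7 (-0.43), Ogn (-0.31), Pcolce (-0.32), Cp (-1.04) and Mgst1 (-2.15). Camera with an estimated correlation kept 16 list calls of 29.

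Replicate number as a block gave 104 and 21 for islets, 4417 and 824 over all tissues, 2782 and 4254 for islets against acini, 1158 and 1431 for MIN6, 84 and 76 for diaphragm and 2569 and 1106 for heart, and Csf1r, Tbx19 and Acrv1 lost their call in heart against muscle. Replicates of the same number correlated across tissues at 0.0097 to 0.018 for islets and acini, -0.040 to 0.0043 for MIN6 and islets, 0.0012 to 0.057 for diaphragm and muscle, and -0.025 to 0.048 for heart and muscle after group means were removed, and no value passed 0.1, so numbers were not treated as pairs.

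Leaving out 1 array at a time gave 96 to 108 genes higher and 18 to 23 lower in islets, 4392 to 4443 and 801 to 862 over all tissues, 2783 to 2875 and 4142 to 4453 for islets against acini, 1153 to 1188 and 1399 to 1459 for MIN6, 68 to 126 and 56 to 119 for diaphragm, and 2426 to 2933 and 1080 to 1115 for heart. Without diaphragm array 2 the diaphragm counts were 126 and 119. Chosen after the data were seen, the run without spleen array 2, adrenal array 1 and adrenal array 3 gave 105 and 22 for islets and 4362 and 824 over all tissues, and Ctf1 lost its call in spleen. The run without acini among the tissues gave 4449 and 848 over all tissues, and a planned run without diaphragm 4659 and 871.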

Other observations

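Islet hormone transcripts were also measured in acini, and unevenly. Ins2 averaged 9347 in acini, 156% of its islet mean, with an SD of 4369. Iapp, made by the same beta cells, averaged 353 or 12.1% of islets, Gcg 1425 or 9.97%, Pyy 248 or 2.77%, Sst 218 or 1.71% and Ppy 220 or 1.43%. The islet genes Slc30a8 and Scg3 averaged 46.7 and 23.7 in acini, near background. On the islet arrays Ins2 averaged 5979, below Gcg (14299), Sst (12738) and Ppy (15334). Whether the Ins2 signal follows the amount of transcript at high levels was not tested, so 156% for Ins2 compares signals only.

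Adrenal array 3 carried more than adipocyte genes. Adipoq was 4216 there, and the brown fat genes Ucp1 and Cidea, chosen after their values were seen, were 569 and 855 against 9 and 31 on adrenal array 1. Ucp1 averaged 6.67 and Cidea 29 in the adipose tissue of this panel. The neutrophil genes S100a8 and S100a9 were 510 and 384 on the same array, and the erythroid gene Alas2 was 731. On adrenal array 1 the sperm genes Tnp1, Prm2 and Ldhc were 605, 444 and 382, against at most 18 on the 2 other adrenal arrays.

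Islets were nearest to MIN6 and, among tissues, to pituitary gland, where the correlation of gene means was 0.865. By the number of genes called, bone marrow and thymus (2930) and spleen and thymus (3038) followed diaphragm and muscle and islets and pituitary gland. By correlation, bone marrow and spleen (0.897) and spleen and thymus (0.893) were closer than islets and pituitary gland. Acini and testis had the most genes called, 9803, followed by eye and testis with 9214, and by correlation brain and testis were furthest apart, at 0.405.

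Sex-linked genes set 2 tissues apart from their sample labels. Ovary and placenta samples were labelled male in the sample records and female in the series text. On the 3 ovary arrays Xist was 1593 to 2139 and Eif2s3y 0 to 6. On placenta arrays 1 and 2 Xist was 2738 and 3136 and Eif2s3y 4 and 3, and on placenta array 3 Xist was 410 and Eif2s3y 243. In MIN6 Xist was 23 to 28 and Eif2s3y 15 to 21.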
